A study of Mus musculus with 3 samples.

How the data were processed

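Dorsal skin of 7 week old C57BL/6 mice was sequenced as 3' transcripts of single cells in 3 libraries, 1 from control skin (normal), 1 from skin treated with imiquimod (IMQ) and 1 from skin treated with imiquimod and celastrol (IMQ+celastrol), per the labels. The deposited values were counts of unique molecular identifiers (UMIs) per gene and cell barcode, made by the authors with Cell Ranger 4.0.0, per the file headers. The genome builds mm10 and GRCm38 were named per the submitters' processing notes. Alignment options and the rule for calling cell barcodes were not given in the sources used here. The lowest barcode held 502, 501 and 500 UMIs in the normal, IMQ and IMQ+celastrol libraries, so shallower barcodes had been left out before deposit and empty droplets could not be used to estimate free RNA. Each matrix held 31053 genes, of which 21796, 21657 and 21268 had a UMI. Barcode sequences shared between libraries numbered 26, 15 and 23 for the pairs normal with IMQ, normal with IMQ+celastrol and IMQ with IMQ+celastrol.

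Depth was 77880943 UMIs over 10565 barcodes in the normal library, 119831835 over 8236 in the IMQ library and 103267738 over 6777 in the IMQ+celastrol library. Cells with fewer than 300 genes (66, 131 and 187 barcodes) or with more than 20% of UMIs from mitochondrial genes (113, 167 and 310 barcodes) were left out. The median mitochondrial share was 1.96%, 2.10% and 2.52%. Doublets were scored in each library with Scrublet as run by scanpy 1.11.5. Where it marked fewer than 0.5% of cells, the top-scoring cells were left out at 0.8% per 1000 cells, a fallback fixed before the data were examined. Scrublet marked 182 normal, 0 IMQ and 92 IMQ+celastrol cells, so the fallback applied to the IMQ library alone and left out 513 cells, or 6.41%, against 1.75% and 1.43% in the others. The libraries were therefore not treated alike, and an alternative with the fallback in all of them left out 870, 513 and 330 cells. Kept cells numbered 10246, 7495 and 6330.

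For clustering, counts of genes seen in at least 10 cells were scaled to 10000 per cell and log-transformed after adding 1, and 2000 variable genes were chosen within libraries with scanpy. Genes were standardized and 30 principal components computed with numpy 2.4.6. The 15 nearest neighbours of each cell were found with scikit-learn 1.9.0, and edges weighted by the Jaccard index of shared neighbours were clustered with the Leiden method at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9). The libraries were clustered together without integration, since a correction would remove treatment and library differences alike. Other steps used Python 3.11.15, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9, with fixed random seeds.

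The 44 clusters were named from 21 marker lists written before the data were examined. A marker counted as detected where at least 25% of the cells of a cluster held a UMI of it. The score of a class was the mean over its markers of the log level relative to the highest cluster, with 0 for markers not detected. A cluster took the class with the highest score if that was at least 0.25 and 1.2 times the next score, if at least 3 markers were detected, and if no other class had more markers among the 10 genes of highest fold. A shallow cluster also needed a marker of its own among these genes. The thresholds were set after the clusters were seen, because a first naming rule had left too many unnamed. By the final rule 10 clusters stayed unnamed, with 27.8%, 11.4% and 13.2% of the kept cells. Their cells counted in the totals of the shares and in no class. Names are written as "-like" because they rest on transcripts alone. Basal and differentiated keratinocyte-like cells were also summed into a keratinocyte-like class. Classes with at least 50 cells in every library were compared, which left 9, so expression in the other classes, neutrophil-like cells among them, was not compared.

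Samples were grouped by the treatment in their labels. Comparisons were IMQ against normal and IMQ+celastrol against IMQ, with IMQ+celastrol against normal as background. With 1 library per group no test was made and no p-value is given. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. For expression, UMIs were summed over the cells of a class in each library and divided by the class total, giving counts per 1000000 UMIs (CPM) with exact Poisson intervals, and ratios of libraries carry exact conditional binomial intervals. All intervals cover counting error and leave out the variation between animals, skin pieces and libraries, which 1 library per group cannot give. Intervals of expression take summed UMIs as Poisson counts. They also leave out variation between the cells of a class, as do the counts of members higher or lower, so they can be too narrow even within a library. Class totals ran from 58903095 UMIs in keratinocyte-like cells of the IMQ+celastrol library to 234301 in lymphatic endothelial-like cells of the normal library, with 359909 in monocyte or macrophage-like cells of the normal library, so precision differed widely between classes. A gene with 0 UMIs in 1 library was given an "at least" fold, with 3 UMIs put in place of 0. This fold is a convention and not the bound of the 95% interval, which was lower for such genes named by size. For Saa3 in monocyte or macrophage-like cells (IMQ over normal) that bound was 332-fold against 408-fold, and for Retnla 849-fold against 1050-fold.

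The 23 gene lists were written from general knowledge before the data were examined. A list was described by the median log2 ratio of its members with at least 20 UMIs in the class over the 3 libraries, after adding 1 CPM. The counting interval of the median came from 200 Poisson redraws. Members were counted as higher or lower where the ratio was at least 1.5-fold and its interval left out 1. The percentile compares the median with 10000 random lists of the same size, matched on expression in 20 bins, and describes these libraries only. There were 582 such comparisons of a list in a class, and the report gives a part of them, chosen by topic and size. When members at 0 UMIs were instead placed at their bound, the epidermal activation median in keratinocyte-like cells for IMQ over normal was 4.56 in place of 4.48, and the signalling list in fibroblast-like cells 1.17 in place of 1.11. Larger moves were seen for the complement list in keratinocyte-like cells (0.83 in place of 0.41) and in monocyte or macrophage-like cells. There, for IMQ over normal, epidermal activation was 1.22 in place of 2.85, the IL-17 and IL-23 axis 1.12 in place of 1.68, LRP1 and its ligands -0.36 in place of -0.10 and the cell cycle -0.75 in place of -0.51, and for IMQ+celastrol over IMQ the matrix protease list was 0.052 in place of -0.28.

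Single genes were named by a rule fixed before the data were examined. In keratinocyte-like, fibroblast-like and monocyte or macrophage-like cells, and in each of the 2 main comparisons, these were the 4 genes highest and the 4 lowest by the interval bound nearest 1. Eligible genes had a ratio of at least 2, at least 50 UMIs and 50 CPM in the higher library, and a class level of at least 0.5 of the level over all kept cells, a guard against free RNA. Mitochondrial, ribosomal protein, Gm, Rik, Xist and Y-linked genes were left out. List members with the most UMIs or the largest ratios were named as examples, and Lrp1 always.

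To follow genes from the first comparison into the second, the IMQ cells of a class were split at random. The 50 genes highest and the 50 lowest in IMQ over normal, among genes with at least 50 UMIs, were chosen with one part, and their ratio of IMQ+celastrol over IMQ was taken from the other part. The share of cells with an Lrp1 UMI was taken after random thinning of every cell to 1500 UMIs, with shallower cells left out. Gene positions came from GENCODE M21, where 407 of 407 gene identifiers were matched.

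The calculations were tested on simulated data drawn from the fibroblast-like profiles with 200 genes changed by known factors. For IMQ over normal (10688 genes), 99.03% of 103 genes changed 2-fold and 100% of 97 changed 4-fold were recovered, the intervals held the true ratio for 95.65% of genes, and 0.105% of unchanged genes passed the rule. For IMQ+celastrol over IMQ (11196 genes) these values were 99% of 100, 100% of 100, 95.11% and 0.136%. In 20 simulations per class without a difference, the median of the high genes was on average -0.0035 with the split and -0.15 without it in fibroblast-like cells, -0.00052 and -0.10 in keratinocyte-like cells, and -0.022 and -0.14 in monocyte or macrophage-like cells. Simulated counts held Poisson error alone.

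Alternatives chosen before the data were examined were a mitochondrial limit of 10%, a minimum of 500 genes, doublets kept, Leiden resolution 2, each library clustered by itself, scaling by the median of ratios, the mean over cells in place of sums, list members with at least 1 UMI, 10 CPM added, 200 genes in place of 50, IMQ cells not split, and no thinning. Doublets left out at a single rate, every cluster named by its highest score, and high and low genes limited to those with a class level of at least 0.5 of that over all kept cells were added after the data were seen. Median-of-ratios scaling shifted log2 ratios by 0.13 in keratinocyte-like cells for IMQ over normal and by -0.14 in fibroblast-like cells for IMQ+celastrol over IMQ. Checks for RNA from other cells and for a changed mix of clusters were also chosen after the results were seen.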

Results

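The study sequenced single cells of dorsal skin from 7 week old C57BL/6 mice in 3 droplet libraries of 3' transcripts, with 1 library per group. The normal library came from control skin. The IMQ library came from skin treated with imiquimod, a Toll-like receptor agonist whose topical use gives mice a psoriasis-like dermatitis. The IMQ+celastrol library came from skin given imiquimod together with celastrol, a plant triterpenoid. The deposited counts are unique molecular identifiers (UMIs) per gene and cell barcode. The normal library held 10565 barcodes and 77880943 UMIs, with a median of 5917 UMIs and 2073 genes per barcode. The IMQ library held 8236 barcodes and 119831835 UMIs (medians 8859 and 2765), and the IMQ+celastrol library 6777 barcodes and 103267738 UMIs (medians 10125 and 3114). After filters, 10246 normal, 7495 IMQ and 6330 IMQ+celastrol cells were kept. Xist UMIs numbered 92897, 60442 and 70731 in these cells, against 3, 1 and 1 UMIs of 4 Y-linked genes. There were no replicates, so no test was made, treatment and library cannot be told apart, and every interval given here is a 95% interval of counting error alone. Intervals of expression thus leave out variation between the cells of a class as well.

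The cells formed 44 clusters, of which 10 stayed unnamed and the others were named by marker genes. Keratinocyte-like cells, the epithelial cells of the epidermis, fell in different clusters in the 3 libraries. In the normal library, 732 were in cluster 12, led by Krt15, 666 in cluster 14, led by Krt77 and Krt10, and 203 in cluster 36, led by Krt15 and Ube2c. None of these 3 clusters held an IMQ cell, and they held 5, 4 and 2 IMQ+celastrol cells. The IMQ cells were mainly in clusters 3 (448 cells, led by Krt1 and Fabp5), 8 (405, Krt14 and Krt6a) and 24 (363, Krt6b and Krt16). Those of the IMQ+celastrol library were mainly in clusters 3 (635 cells), 17 (529, Stfa3 and Krt5) and 8 (390). Among fibroblast-like cells, the normal library led clusters 0 (1337 cells, Col1a1 and Mfap4) and 15 (625, Col11a1 and Lrrc15). The IMQ library led cluster 1 (1084 cells, Tnc, Mmp3 and Saa3) and cluster 10 (507, Saa3 and Cxcl12). IMQ+celastrol cells were spread more evenly, with 423 in cluster 2, 379 in cluster 6, 343 in cluster 7, 279 in cluster 1 and 276 in cluster 10. Of the monocyte or macrophage-like cells, cluster 37, led by Ccl8, C1qb and Pf4, held 116 normal, 57 IMQ and 17 IMQ+celastrol cells, and cluster 16, led by Lyz2 and Chil3, held 24, 504 and 91. A cluster made mostly of 1 library may be that library and not a cell type, and several leading genes were also naming markers, so values within a class also carry its mix of clusters.

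The first comparison, IMQ against normal, addressed what the imiquimod model looked like in this skin. Monocyte or macrophage-like cells made up 7.49% of the kept IMQ cells (6.90 to 8.10) and 1.37% of the normal cells (1.15 to 1.61), a 5.48-fold higher share (4.54 to 6.64). Neutrophil-like cells, which enter skin in acute inflammation, made up 1.84% (138 cells, 1.55 to 2.17) against 0.0683% (7 cells, 0.0275 to 0.141). Fibroblast-like cells, the matrix-producing cells of the dermis, made up 40.7% (39.6 to 41.8) against 28.2% (27.3 to 29.0). Pericyte or smooth muscle-like and lymphatic endothelial-like shares were 3.31-fold (2.85 to 3.85) and 4.15-fold (3.08 to 5.65) higher in the IMQ library, and the dendritic cell-like share was 5.09-fold lower (3.75 to 7.04). The keratinocyte-like share was 17.2% (16.4 to 18.1) against 18.7% (18.0 to 19.5), with 6.38% basal-like and 10.8% differentiated-like cells in the IMQ library against 12.0% and 6.67% in the normal library. Hair follicle keratinocyte-like cells numbered 585 in the normal library and 1 in each of the others. Unnamed clusters 4, 20, 22 and 25 held 884, 536, 525 and 416 normal cells against 22, 0, 0 and 2 IMQ cells. Shares depend on one another, so this near absence by itself raises the IMQ shares of all other classes against the normal library. The shares, that of fibroblast-like cells included, were not recomputed without these cells. Unnamed clusters held 27.8% of the normal, 11.4% of the IMQ and 13.2% of the IMQ+celastrol cells, and the median kept cell held 5925 UMIs in the normal library, 8862 in the IMQ library and 10642 in the IMQ+celastrol library. With called doublets kept, the log2 ratio of the monocyte or macrophage-like share was 0.87 in place of 2.45, and with every cluster named by its highest score that of the keratinocyte-like share was -1.09 in place of -0.12, while it turned to 0.10 with each library clustered by itself.

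In keratinocyte-like cells of the IMQ library, genes of the activated epidermis were higher throughout the list and barrier genes were mostly lower. All 20 measured members of the epidermal activation list were at least 1.5-fold higher, with a median log2 ratio of 4.48, above each of 10000 random lists matched on expression (percentile 100). S100a8 and S100a9, which encode the subunits of the alarmin calprotectin, were 684-fold (620 to 756) and 608-fold (556 to 666) higher, at 14874 and 15804 counts per 1000000 UMIs of the class (CPM). The hyperproliferation keratins Krt16 and Krt6a were 20.4-fold (19.9 to 20.9) and 57.3-fold (54.4 to 60.4) higher. Of 15 cornified envelope and barrier genes, 10 were lower and 1, Krt1, was higher, with a median of -1.62 (percentile 0). Lor, which encodes the main cornified envelope protein loricrin, was 203-fold lower (169 to 246), Flg, for filaggrin, 33.2-fold lower (29.97 to 36.96) and Krt10 3.09-fold lower (3.07 to 3.12). Lor, Flg, Krt10 and Krt1 were among the markers that named these clusters, and the log2 ratio of Lor was -3.27 in place of -7.66 with doublets left out at a single rate in every library.

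Metabolic and stress lists were also higher in the keratinocyte-like cells. Of 17 glycolysis and hypoxia genes, 14 were higher and none lower (median 1.35, percentile 100), among them Gapdh at 2.93-fold (2.88 to 2.98) and Egln3, an oxygen-sensing hydroxylase, at 3.42-fold (3.09 to 3.81). Of 16 targets of the oxidative stress factor NRF2, 11 were higher and none lower (1.07), with the cystine transporter gene Slc7a11 at 52.6-fold (37.6 to 76.1) and the glutathione transferase gene Gsta4 at 29.4-fold (26.4 to 32.7). Lipid and cholesterol synthesis genes were higher for 9 of 16 (0.71), and heat shock genes for 8 of 14 with 1 lower (0.65). NF-kB targets were higher for 10 of 18 and lower for 1 (0.85), with the neutrophil attractant Cxcl2 at 38.8-fold (32.6 to 46.5). The chemokine list went both ways, with 10 of 22 higher and 7 lower: Cxcl3 had no UMI in the normal cells and was at least 216-fold higher, while the skin-homing chemokine Ccl27a was 34.7-fold lower (32.8 to 36.7). Interferon response genes were lower for 10 of 20 and higher for 2 (-0.43, percentile 2.14), with Ifi27l2a 15.2-fold lower (13.3 to 17.4), and MHC class II genes lower for 6 of 7 and higher for 1 (-0.99). The MHC class II list was also lower in fibroblast-like cells (5 of 7 lower and 1 higher, -1.61), and the share of dendritic cell-like cells, which are rich in these transcripts, was lower too, so a change in free RNA is not excluded. By the fixed rule of size, the largest keratinocyte-like ratios were those of Sprr2d (1774.5-fold, 965 to 3701), S100a8, S100a9 and Sprr2i, which had 1 UMI in the normal cells and was 2197-fold higher (394 to 86808). The lowest were those of Krt77 (3854-fold lower, 2861 to 5326), Flg2 (0 UMIs in the IMQ cells against 943, at least 882-fold lower), Sema3d (376-fold lower, 219 to 708) and Lor. Under the alternative settings the log2 ratio reached 11.84 for Sprr2d (10.79 as reported), 12.32 for Sprr2i (11.10), 10.39 for S100a8 (9.42), 10.18 for S100a9 (9.25), -10.93 for Krt77 (-11.91) and -7.51 for Sema3d (-8.55).

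Fibroblast-like cells of the IMQ library carried more transcripts of chemokines, complement factors and matrix proteases, and fewer of several matrix proteins. Of 22 chemokine genes, 14 were higher and 4 lower (median log2 ratio 1.04, percentile 100). Cxcl12, a chemokine that draws CXCR4-bearing leukocytes, was 6.61-fold higher (6.40 to 6.83), and Ccl2 and Ccl7, which attract monocytes, were 4.59-fold (4.38 to 4.81) and 4.42-fold (4.22 to 4.63) higher, while Ccl19 was 2.64-fold lower (2.48 to 2.80). The chemokine median was 0.19 with 10 CPM added before the logarithm in place of 1. Complement genes were higher for 12 of 14 and lower for 1 (1.44), with C3 at 13.03-fold (12.5 to 13.6) and Cfb at 16.2-fold (13.1 to 20.4). Matrix proteases and their inhibitors were higher for 14 of 16 (1.45, or 1.64 with genes at 0 placed at their bound), with Mmp3, for stromelysin, at 8.06-fold (7.75 to 8.39) and Timp1 at 5.98-fold (5.75 to 6.23). The list of fibroblast and macrophage signalling genes had 21 of 34 higher and 5 lower (1.11), among them the cytokine genes Spp1 at 40.5-fold (33.5 to 49.4) and Il33 at 10.6-fold (9.05 to 12.4).

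Matrix genes of the fibroblast-like cells were lower for 10 of 22 and higher for 5 (-0.52, percentile 0.03). The collagen gene Col1a1 was 4.58-fold lower (4.55 to 4.61) and Mfap4, for a microfibril-associated protein, 7.29-fold lower (7.13 to 7.45), while Tnc, for tenascin C, was 13.8-fold higher (13.2 to 14.4). Cell cycle genes were lower for 18 of 20 (-1.35), including Stmn1 (7.83-fold, 7.24 to 8.47) and Top2a (3.77-fold, 3.26 to 4.35). Stmn1 is also a leading gene of clusters 19 and 22, which held 585 and 525 normal cells against 1 and 0 IMQ cells. Free RNA of these cells as a part of the normal level was not tested for this list. NF-kB targets were higher for 10 of 17 with 1 lower (0.78), with Ptgs2, for cyclooxygenase, at 4.44-fold (4.03 to 4.90) and Il6 at 3.84-fold (3.58 to 4.13), and immediate early genes were higher for 8 of 18 (0.57). Interferon response genes had 6 of 21 lower and 2 higher (-0.20, percentile 6.45), and their median was 0.027 with every cluster named by its highest score. The genes named by the rule of size were Saa3, an acute-phase serum amyloid gene (7568-fold, 5599 to 10501), Lcn2, for the siderophore-binding lipocalin (2261-fold, 1448 to 3755), Hp, for haptoglobin (529-fold, 257 to 1316), and Cxcl13, a B cell chemokine (335-fold, 267 to 425). On the lower side stood Igfbp2 (254-fold, 211 to 309), Adamts18 (138-fold, 83.1 to 247), Stmn2 (73.7-fold, 58.6 to 93.8) and Acan, for aggrecan (68.9-fold, 47.4 to 104). Under the alternative settings the log2 ratio of Saa3 ran from 11.35 to 14.39 (12.89 as reported), and it reached 6.01 for Cxcl13 (8.39), 12.69 for Lcn2 (11.14), -4.40 for Acan (-6.11) and -5.16 for Stmn2 (-6.20). Saa3 leads 2 of the fibroblast-like clusters rich in IMQ cells, and Col1a1 and Mfap4 lead the cluster with most normal cells. Igfbp2 is among the leading genes of clusters 0 and 15, with 1337 and 625 normal against 10 and 1 IMQ cells. Its ratio therefore also carries the mix of clusters, and no value with the same mix was computed.

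Monocyte or macrophage-like cells of the IMQ library carried fewer transcripts of tissue-resident macrophages and of antigen presentation, and more of NF-kB targets. Of 16 tissue-resident or repair macrophage genes, 12 were lower and 2 higher (median -2.81, percentile 0), with Pf4 26.9-fold lower (24.2 to 29.9) and the mannose receptor gene Mrc1 5.55-fold lower (4.84 to 6.34). MHC class II genes were lower for 7 of 10 (-1.66), with the invariant chain gene Cd74 10.2-fold lower (9.75 to 10.6) and H2-Ab1 14.6-fold lower (13.6 to 15.6). NF-kB targets were higher for 12 of 17 (1.19) and inflammatory macrophage genes for 7 of 15 with 2 lower (0.84): Il1b was 5.71-fold higher (4.69 to 7.03), Ccl3 3.25-fold higher (2.73 to 3.90), and Il6, with no UMI in the normal cells, at least 4.56-fold higher. Chemokine genes were lower for 9 of 19 and higher for 4 (-0.86), and complement genes lower for 9 of 13 and higher for 1 (-1.38), with C1qa 4.71-fold lower (4.38 to 5.07) and C3 5.88-fold higher (3.60 to 10.3). The rule of size named Saa3 (at least 408-fold higher), Wfdc21 (205-fold, 36.8 to 8116, 1 UMI in the normal cells), Mmp8 (58.0-fold, 16.0 to 479, 2 UMIs) and the chitinase-like gene Chil3 (35.2-fold, 26.9 to 47.0). It also named Ccl8 (1488-fold lower, 900 to 2663), Retnla (at least 1050-fold lower), Cd209d (at least 374-fold lower) and Cd209f (1009-fold lower, 177 to 40263, 1 UMI in the IMQ cells). Pf4, C1qa and Ccl8 lead the cluster that held 116 of the 140 normal cells, and Chil3 leads the one that held 504 of the 561 IMQ cells. With called doublets kept the log2 ratio of Ccl8 was -6.78 in place of -10.54, that of Chil3 7.48 in place of 5.14, that of Mmp8 8.20 in place of 5.86 and that of Cd209f -7.76 in place of -9.98. With each library clustered by itself that of Wfdc21 was 5.09 in place of 7.68. The Col1a1 level in these cells, taken as a measure of RNA from other cells, was 956 CPM in the normal, 32.1 in the IMQ and 223 in the IMQ+celastrol library.

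T cell-like cells of the IMQ library carried more transcripts of the IL-17 and IL-23 axis, the cytokine pathway targeted in psoriasis, with 9 of 10 measured genes higher and a median log2 ratio of 2.31 (percentile 100). Il17a was 6.94-fold higher (6.38 to 7.56), Il17f 42.2-fold higher (33.5 to 53.8) and Il22 241-fold higher (144 to 442). These 3 genes lead cluster 27, which held 69 of the 452 normal, 236 of the 501 IMQ and 108 of the 251 IMQ+celastrol T cell-like cells. The T cell-like share was 6.68% of the IMQ and 4.41% of the normal cells, and its log2 ratio of 0.60 turned to -0.029 with each library clustered by itself.

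The second and main comparison, IMQ+celastrol against IMQ, addressed what differed when celastrol was given with imiquimod. Monocyte or macrophage-like cells made up 1.71% of the IMQ+celastrol cells (1.40 to 2.06), a 4.39-fold lower share than in the IMQ library (3.57 to 5.44). With called doublets kept its log2 ratio was -1.91 in place of -2.13, larger in size than the 0.87 of IMQ over normal at that setting, so the place of this share relative to the normal library depends on the doublets. Neutrophil-like cells made up 1.14% (72 cells, 0.891 to 1.43), 1.62-fold lower (1.21 to 2.18), and T cell-like cells 3.97% (3.498 to 4.476), 1.69-fold lower (1.45 to 1.97). Keratinocyte-like cells made up 30.3% (29.2 to 31.4), 1.76-fold higher (1.64 to 1.89), with basal-like cells at 18.4% and differentiated-like cells at 11.9%. Fibroblast-like cells made up 34.4% (33.3 to 35.6), 1.18-fold lower (1.12 to 1.25). The log2 ratio of the keratinocyte-like share was 0.12 with each library clustered by itself, in place of 0.82.

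In keratinocyte-like cells, 17 of 20 epidermal activation genes were lower in the IMQ+celastrol library and none was higher (median log2 ratio -1.05, percentile 0). The mix of this class differed as well, with 478 of 1289 cells basal-like in the IMQ library and 1165 of 1917 in the IMQ+celastrol library. Cluster 24, led by Krt6b, Sprr1b and Krt16, held 363 IMQ and 113 IMQ+celastrol cells, and cluster 17 held 10 and 529. No value with the same mix of clusters was computed for this class, so a lower level per cell and another mix are not told apart. S100a8 and S100a9 were 5.97-fold (5.94 to 6.01) and 8.03-fold (7.98 to 8.08) lower and Lcn2 7.33-fold lower (7.02 to 7.65), while Fabp5, a fatty acid binding protein gene with the most UMIs of the list, was 1.48-fold lower (1.47 to 1.48) and Stfa3 1.11-fold higher (1.11 to 1.12). Barrier genes were higher for 5 of 15 and lower for none (0.29, percentile 99.9), with Flg 5.67-fold (5.10 to 6.33) and Krt10 1.96-fold (1.94 to 1.98) higher, while Lor stood at 2.26 CPM against 2.21 CPM, with a ratio of 1.02 (0.792 to 1.33). Interferon response genes were higher for 12 of 20 and lower for 1 (0.57, percentile 100), among them Ifi27l2a (3.78-fold, 3.30 to 4.35), Gbp2 (2.26-fold, 1.84 to 2.80) and Isg15 (1.76-fold, 1.51 to 2.07). NRF2 targets were lower for 9 of 16 (-0.59), with Slc7a11 5.68-fold (5.31 to 6.09) and Gsta4 3.59-fold (3.51 to 3.68) lower, and lipid and cholesterol synthesis genes were lower for 7 of 16 (-0.48), with Scd2 2.85-fold lower (2.75 to 2.95). NF-kB targets were lower for 6 of 18 and higher for 2 (-0.23), and chemokine genes lower for 7 of 22 and higher for 5 (-0.24), with Cxcl2 4.40-fold lower (4.24 to 4.57), Ccl20 2.95-fold lower (2.81 to 3.08) and Ccl27a 4.2-fold higher (3.96 to 4.46). Only 1 of 17 glycolysis and hypoxia genes was lower by 1.5-fold (-0.30). The rule of size named Krt15 (15.9-fold higher, 15.1 to 16.7), Mt4 (8.67-fold, 8.06 to 9.33), Ccl27a and Dapl1 (4.15-fold, 3.81 to 4.52), and on the lower side Sprr2e (8.99-fold, 8.52 to 9.50), S100a9, Uox (7.46-fold, 6.75 to 8.26) and Sprr2j-ps (6.69-fold, 6.21 to 7.21). Sprr2 genes are near-identical neighbours between which the authors' counting can split reads, and Krt15 and Krt10 were naming markers. Under the alternative settings the log2 ratio reached 3.02 for Krt15 (3.99 as reported), 2.25 for Mt4 (3.12) and 1.14 for Ccl27a (2.07).

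**Figure D1:**
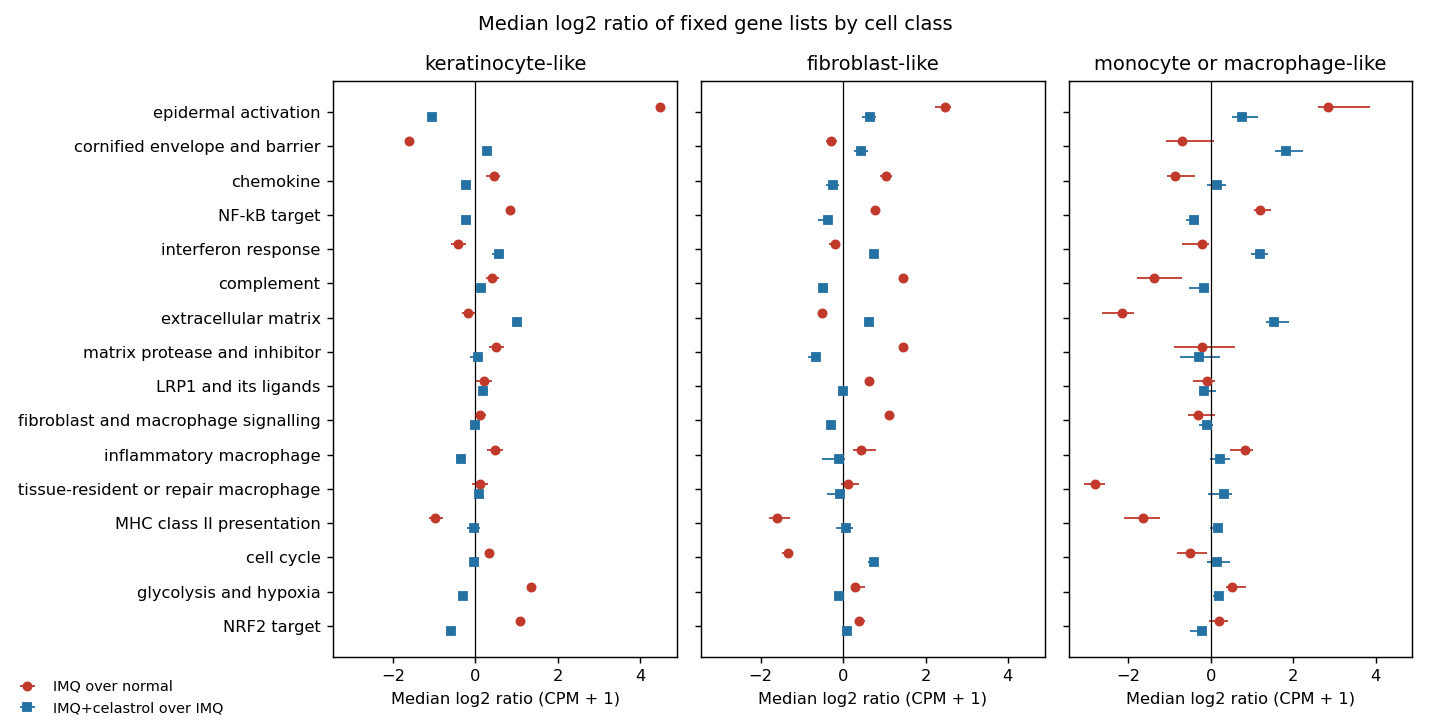
Median log2 ratio of 16 of the 23 gene lists in keratinocyte-like, fibroblast-like and monocyte or macrophage-like cells, for IMQ over normal and for IMQ+celastrol over IMQ, with bars for the 95% counting interval of each median. In keratinocyte-like cells the epidermal activation list stood at 4.48 and -1.05, and in fibroblast-like cells the interferon response list at -0.20 and 0.74.

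Fibroblast-like cells of the IMQ+celastrol library carried fewer transcripts of complement factors, matrix proteases and NF-kB targets than those of the IMQ library, and more of matrix, interferon response and cell cycle genes. Complement genes were lower for 7 of 14 (median -0.48), with Cfb 3.04-fold (2.78 to 3.31) and C3 1.63-fold (1.61 to 1.65) lower and C4b at a ratio of 1.01 (0.987 to 1.04). Proteases and inhibitors were lower for 9 of 16 and higher for 1 (-0.67), with Mmp3 2.28-fold lower (2.24 to 2.33), and NF-kB targets lower for 8 of 17 and higher for 1 (-0.38), with Ptgs2 2.59-fold (2.42 to 2.77) and Il6 2.41-fold (2.29 to 2.53) lower. Chemokine genes were lower for 8 of 22 and higher for 4 (-0.25): Ccl2 was 2.44-fold lower (2.36 to 2.52), Cxcl12 2.13-fold lower (2.10 to 2.17) and Ccl8 2.17-fold higher (2.05 to 2.31). Of the fibroblast and macrophage signalling genes, 13 of 34 were lower and 4 higher (-0.30), with Spp1 7.04-fold lower (6.57 to 7.56). Immediate early genes were lower for 5 of 18 (-0.37).

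Matrix genes of the fibroblast-like cells were higher for 12 of 22 and lower for 2 (0.63, percentile 100), with Mfap4 3.02-fold (2.95 to 3.10) and Col1a1 1.98-fold (1.97 to 1.999) higher and Tnc 2.60-fold lower (2.55 to 2.64). Col1a1 and Mfap4 lead cluster 0, which held 201 IMQ+celastrol and 10 IMQ cells. Matrix genes were not recomputed with the same mix of clusters in both libraries, so another mix is not excluded. Interferon response genes were higher for 15 of 21 and lower for none (0.74, percentile 100), with Ifi27l2a at 2.97-fold (2.89 to 3.06), Bst2, for tetherin, at 1.97-fold (1.88 to 2.06) and Oas1a, a sensor of viral RNA, at 2.95-fold (2.18 to 4.02). Cell cycle genes were higher for 14 of 20 (0.76), including Stmn1 (2.58-fold, 2.36 to 2.82) and Top2a (2.27-fold, 1.96 to 2.64). The rule of size named Igfbp2 (15.7-fold higher, 12.9 to 19.3), Lrrc17 (4.79-fold, 4.40 to 5.21), Lrrc15 (4.26-fold, 3.93 to 4.63) and Mmp16 (3.72-fold, 3.34 to 4.16). On the lower side it named Cfd, for the adipocyte protease adipsin (253-fold, 123 to 631), Hp (40.4-fold, 33.9 to 48.5), Saa1 (19.6-fold, 16.9 to 22.8) and the adipocyte gene Fabp4 (16.1-fold, 14.1 to 18.4), while Saa3 was 10.3-fold lower (10.2 to 10.4). Cfd stood at 0.604, 85.2 and 0.336 CPM in the normal, IMQ and IMQ+celastrol libraries, and Fabp4 at 13.3, 185.5 and 11.5. Both are on the adipocyte marker list, and no cluster took that name. Fabp4 also leads the vascular endothelial-like cluster 30. Free RNA of adipocytes or of endothelial cells as a part of their IMQ level was not tested. Igfbp2 and Lrrc15 are among the leading genes of cluster 15, which held 31 IMQ+celastrol cells and 1 IMQ cell. The log2 ratio of Hp reached -4.53 (-5.34 as reported) and that of Cfd -7.32 (-7.99) under the alternative settings. Scaling by the median of ratios moved the log2 ratios of this class by -0.14 in this comparison, and those of keratinocyte-like cells by 0.13 in the comparison of IMQ with normal. RNA of keratinocytes was also more frequent outside them in the IMQ+celastrol library: Krt14 stood at 342 CPM in fibroblast-like cells against 71.7 in the IMQ library and 91.2 in the normal library.

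Monocyte or macrophage-like cells numbered 108 in the IMQ+celastrol library. Their interferon response genes were higher than in the IMQ library for 15 of 20 and lower for none (median log2 ratio 1.2, percentile 100), with Ifit1 at 11.5-fold (9.44 to 14.1), Rsad2, for the antiviral protein viperin, at 7.96-fold (6.85 to 9.25) and Isg15 at 3.89-fold (3.44 to 4.39). NF-kB targets were lower for 3 of 17 and higher for 1 (-0.40, percentile 0.03), with Il1b 1.54-fold lower (1.42 to 1.68). Inflammatory macrophage genes were higher for 5 of 15 and lower for 2 (0.23), with Ccl4 at 2.37-fold (2.30 to 2.44), and chemokine genes higher for 6 of 19 and lower for 3 (0.14). Tissue-resident or repair macrophage genes were higher for 5 of 16 and lower for 4 (0.33), with Pf4 at 2.40-fold (2.02 to 2.85), and none of 10 MHC class II genes differed by 1.5-fold (0.18). The rule of size named Coch (124-fold, 71.3 to 236), Igfbp5 (107-fold, 50.4 to 272), Ifit1 and Ccl5 (10.1-fold, 7.98 to 12.9) on the higher side, and Saa3 (4.60-fold lower, 4.18 to 5.07), Acp5 (3.66-fold, 2.59 to 5.32), Clec4d (3.43-fold, 2.47 to 4.90) and Tnfsf9 (3.29-fold, 2.42 to 4.58) on the lower. Coch and Igfbp5 are also among the leading genes of fibroblast-like clusters, and the Col1a1 level of these cells was higher as well. With doublets left out at a single rate in every library the log2 ratio of Coch turned to -0.87 in place of 6.96 and that of Igfbp5 was 1.84 in place of 6.74, and with called doublets kept Ccl5 was at 1.54 in place of 3.34, Ifit1 at 2.33 in place of 3.53 and Saa3 at -3.38 in place of -2.20.

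In T cell-like cells, 5 of 10 genes of the IL-17 and IL-23 axis were lower in the IMQ+celastrol library and none higher (median -0.65, percentile 0.01). Il17a was 2.48-fold lower (2.31 to 2.67), Il17f 3.02-fold lower (2.76 to 3.31) and Il22 7.27-fold lower (6.38 to 8.31).

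Genes that differed most between IMQ and normal were then followed into the IMQ+celastrol library, with the IMQ cells split at random so that the genes were chosen in one part and compared in the other. The 50 genes highest in IMQ over normal had a median log2 ratio of IMQ+celastrol over IMQ of -1.68 in keratinocyte-like cells, where all 50 were lower, and of -1.65 in fibroblast-like cells, where 49 were lower (percentile 0 for both). The 50 genes lowest in IMQ over normal stood at 1.67 in keratinocyte-like cells (46 higher) and 1.04 in fibroblast-like cells (45 higher, percentile 100 for both). In monocyte or macrophage-like cells the corresponding medians were -0.25 (32 lower, percentile 1.23) and 0.66 (39 higher, percentile 100). The fibroblast-like high genes included Saa3, Lcn2, C3 and Tnc, besides S100a8, S100a9, Krt6b and the haemoglobin genes Hba-a1 and Hbb-bs, which are abundant in other cells. Among the fibroblast-like low genes, Krt15 (2.47), Fxyd3 (2.34), Cst6 (1.71) and Krt77 (0.47) lead clusters that are not fibroblast-like. Igfbp2 (3.40), Lrrc15 (1.95), Tnmd (1.53), Col11a1 (1.15) and Ednrb (-1.07) lead cluster 15, with 625 normal, 1 IMQ and 31 IMQ+celastrol cells. Values with the same mix of clusters were computed for the fibroblast-like high genes alone, so another mix is not excluded for the other sets. The low genes of monocyte or macrophage-like cells likewise included genes of fibroblasts and keratinocytes, such as Mfap4 (5.76), Lum (4.02), Col1a1 (3.56) and Krt5 (2.43), while macrophage genes went both ways, with Mrc1 (-0.55), Clec10a (-0.18) and Igf1 (0.16) near or below 0 and Pf4 (1.14) and Retnla (5.97) above. Their high genes included Retnlg, S100a8, S100a9 and G0s2, which neutrophils also express. These genes were picked after their values were seen. With only genes whose class level was at least 0.5 of that over all kept cells, a setting added after the data were seen, the low genes of this class had a median of 0.39 and the high genes of -0.32. In simulated libraries without any difference the split gave means for the high genes of -0.0035 (range -0.055 to 0.052) in fibroblast-like, -0.00052 (-0.031 to 0.045) in keratinocyte-like and -0.022 (-0.16 to 0.12) in monocyte or macrophage-like cells, and no split gave -0.15, -0.10 and -0.14. Variation of the IMQ library as a whole stays in both comparisons. With 200 genes the keratinocyte-like medians were -0.88 and 0.99, at Leiden resolution 2 that of the low genes was 0.84, and with doublets kept that of the high genes in monocyte or macrophage-like cells was -1.01.

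**Figure D2:**
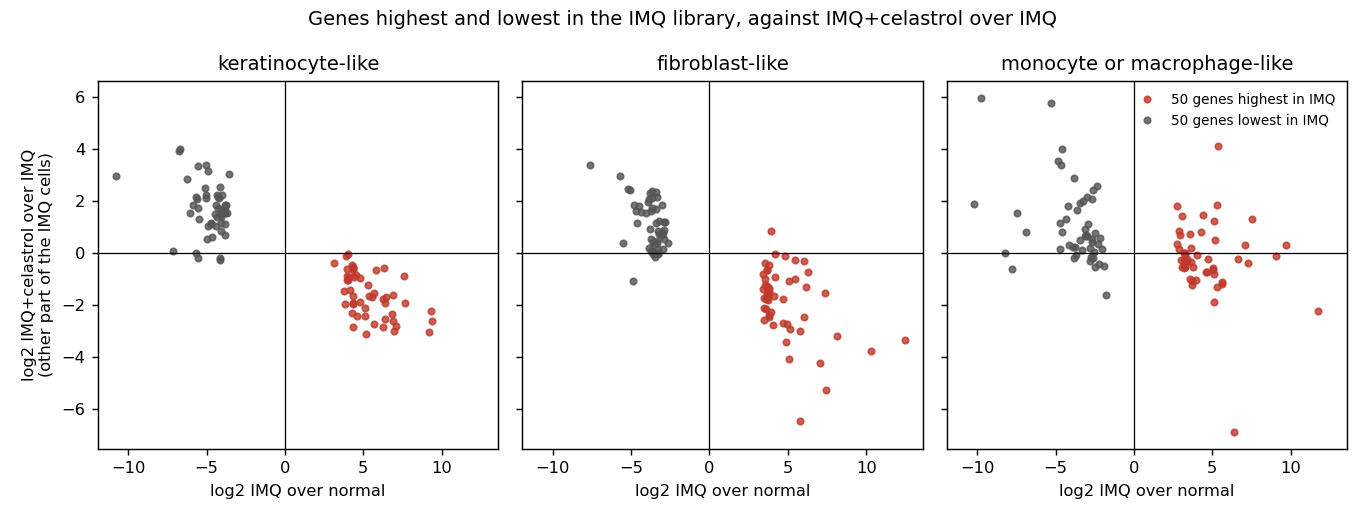
Log2 ratio of IMQ+celastrol over the held-out IMQ cells against the log2 ratio of IMQ over normal, for the 50 genes highest and the 50 lowest in IMQ over normal, in keratinocyte-like, fibroblast-like and monocyte or macrophage-like cells; each point is a gene. The horizontal values used all IMQ cells of the class, the held-out cells included, while the genes were chosen without the held-out cells. The high genes had medians of -1.68, -1.65 and -0.25, and the low genes of 1.67, 1.04 and 0.66.

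Lrp1, named in the series title as the target of celastrol, encodes a large endocytic receptor (ENSMUSG00000040249; chromosome 10, positions 127538161 to 127621148 on the minus strand of GRCm38, a protein-coding gene in GENCODE M21). Its level was highest in fibroblast-like cells among the 9 classes compared, at 586 CPM in the normal library (574 to 599), 1510.0 in the IMQ library (1496 to 1524) and 1113 in the IMQ+celastrol library (1099 to 1127), giving log2 ratios of 1.37 for IMQ over normal and -0.44 for IMQ+celastrol over IMQ. These ratios also carry the mix of clusters. Clusters 0 and 15 held 1337 and 625 normal against 10 and 1 IMQ cells, and clusters 1 and 10 held 1084 and 507 IMQ against 279 and 276 IMQ+celastrol cells. No Lrp1 value with the same mix was computed. After every cell was thinned to 1500 UMIs, 58.7% (56.7 to 60.6), 84.0% (82.6 to 85.3) and 72.7% (70.8 to 74.6) of fibroblast-like cells had an Lrp1 UMI, with 279, 90 and 32 shallower cells left out, and without thinning 85.2%, 96.7% and 94.1% did, at median depths of 4352, 8746 and 8840 UMIs. In monocyte or macrophage-like cells Lrp1 stood at 150.0 CPM (113 to 196), 222 CPM (207 to 238) and 188 CPM (155 to 227), log2 ratios of 0.57 and -0.24. The counting interval of the latter was -0.54 to 0.05, so no difference between the IMQ+celastrol and IMQ libraries was detectable in this class at this depth. Thinned shares were 19.1%, 28.1% and 25.5% with 51, 63 and 14 cells left out, and shares without thinning 30.7%, 66.0% and 54.6%, at median depths of 2120, 6942 and 5239 UMIs. T cell-like cells gave a background, with thinned shares of 0.464%, 1.34% and 0.909% (21, 52 and 31 cells left out), shares without thinning of 0.885%, 3.59% and 1.59%, and median depths of 2928, 2787 and 2199 UMIs. This background is too low for monocyte or macrophage-like cells, which carried more Col1a1 than T cell-like cells, unequally by library (956 against 21.4 CPM in the normal, 32.1 against 24.5 in the IMQ and 223 against 122 in the IMQ+celastrol library), so RNA of fibroblasts is not excluded as part of their Lrp1 level and ratios. With doublets kept, the monocyte or macrophage-like log2 ratios were 1.66 and -0.92.

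The list of LRP1 and its ligands was higher for 11 of 18 genes and lower for 2 in fibroblast-like cells of the IMQ against the normal library (median 0.62, percentile 99.98). Serpine2, for a protease inhibitor cleared through the receptor, was 5.86-fold higher (5.23 to 6.58), and the growth factor gene Ptn was 40.4-fold lower (24.1 to 73.2). Ptn is also a leading gene of clusters 4, 19 and 22, which held 884, 585 and 525 normal cells against 22, 1 and 0 IMQ cells. Free RNA of these cells as a part of its normal level was not tested. Between the IMQ+celastrol and IMQ libraries the list had 3 genes higher, 3 lower and a median of 0.0011 (percentile 10.54). Serpine2 was 2.08-fold lower (1.96 to 2.22), Ptn 11.5-fold higher (6.70 to 21.2) and Apoe, for an apolipoprotein ligand, 1.86-fold higher (1.82 to 1.90).

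**Figure D3:**
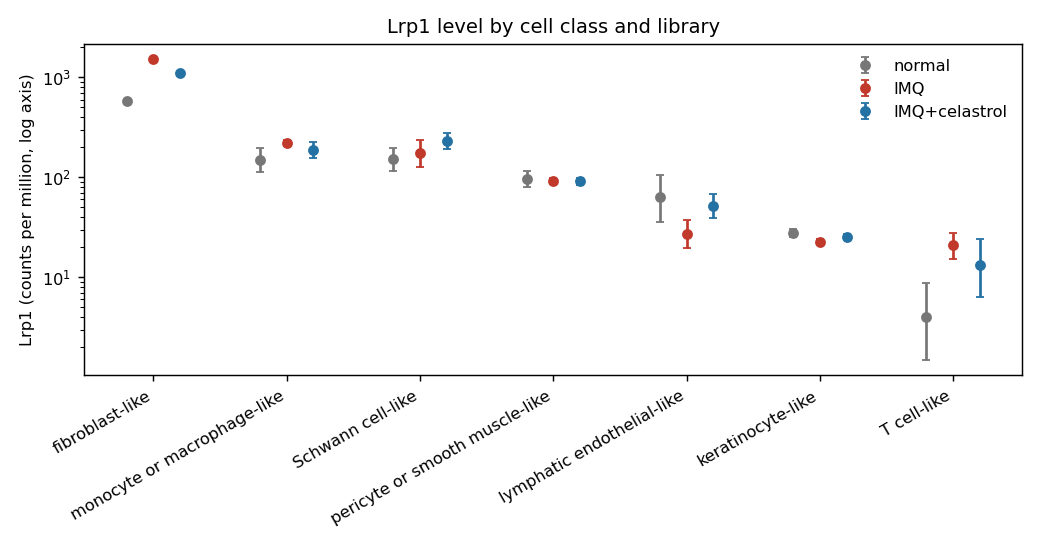
Lrp1 in counts per 1000000 UMIs of each class (CPM), on a log axis for the normal, IMQ and IMQ+celastrol libraries, with exact 95% Poisson intervals of counting error. Fibroblast-like cells stood at 586, 1510.0 and 1113 and T cell-like cells at 4.01, 20.8 and 13.1.

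IMQ+celastrol against normal, the background comparison, shows where the values of the treated library lay relative to control skin. In keratinocyte-like cells 19 of 20 epidermal activation genes were still higher than in the normal library (median 3.72), with S100a8 at 115-fold (104 to 127), and 10 of 15 barrier genes were lower and 1 higher (-1.33), with Krt10 at a ratio of 0.633 (0.628 to 0.638). Fibroblast-like chemokine genes were higher for 12 of 22 and lower for 3 (0.72), complement genes higher for 9 of 14 and lower for 1 (0.88) and matrix genes higher for 7 and lower for 6 of 22 (0.24), with Saa3 at 737-fold (545 to 1022) and Col1a1 at a ratio of 0.433 (0.431 to 0.436). Interferon response genes were higher than in the normal library for 11 of 21 with 1 lower in fibroblast-like cells (0.58), and for 11 of 20 with none lower in monocyte or macrophage-like cells (0.89). Tissue-resident or repair macrophage genes were lower for 14 of 16 and higher for 1 (-2.81), and the IL-17 and IL-23 axis was higher for 7 of 10 genes in T cell-like cells (1.62), with Il17a at 2.80-fold (2.52 to 3.11).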

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

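All tests of explanations in this part were chosen after the result was seen, and their bounds were set when exploratory values were known. Each difference between classes given here was not tested. The chemokine list went opposite ways between IMQ and normal in fibroblast-like cells (median log2 ratio 1.035) and in monocyte or macrophage-like cells (-0.862), a difference of 1.897. The complement list likewise stood at 1.441 in fibroblast-like and -1.381 in monocyte or macrophage-like cells, a difference of 2.822. Between IMQ+celastrol and IMQ, the epidermal activation list was 0.648 in fibroblast-like and -1.045 in keratinocyte-like cells, a difference of 1.693, and 0.759 in monocyte or macrophage-like cells, a difference of 1.804 from keratinocyte-like cells. In that comparison Krt14 in T cell-like cells stood at 2.48% of the keratinocyte-like level in the IMQ+celastrol library, 1.03% in the IMQ library and 0.697% in the normal library.

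Interferon response genes were higher in fibroblast-like cells of the IMQ+celastrol than of the IMQ library. Free RNA from other cells as the whole source is argued against by T cell-like cells, where the summed level of the list differed by 195.5 CPM against 779 CPM in fibroblast-like cells, or 25.08% (upper bound 32.8%, from counting error in the T cell-like sums alone), and by 2 of the 19 members with any rise in fibroblast-like cells rising there by as many CPM. T cell-like cells may express these genes themselves, so a fall in their own expression could hide free RNA. Their whole level in the IMQ+celastrol library, 581 CPM, was still below the rise of 779 CPM in fibroblast-like cells. Another mix of fibroblast-like clusters is argued against as the whole cause, since over the 6 clusters with at least 50 cells in both libraries, taken in the same mix, the median log2 ratio was 0.510 (0.472 to 0.687) in place of 0.74, and it ran from -0.02 in cluster 7 to 1.18 in cluster 10. Clusters 0 and 15, with 201 and 31 IMQ+celastrol cells against 10 and 1 IMQ cells, stayed out of this value. A mix within clusters, a smaller part from either source and variation between animals or libraries stay open. A response to celastrol may be a biological explanation, as a hypothesis that 1 library per group leaves untested.

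The 50 genes highest in the IMQ library were lower in the IMQ+celastrol library in fibroblast-like cells. Free RNA from other cells is argued against for the set, as 4 of the 50 genes were lower in T cell-like cells by as many CPM as in fibroblast-like cells. Over the same 6 clusters, taken in the same mix in both libraries, the median log2 ratio was -1.344 (-1.382 to -1.265) in place of -1.65, which argues against another mix of these clusters as the whole cause, with clusters 0 and 15 again left out. By cluster the median ran from -1.652 in cluster 10 to -0.41 in cluster 6, where 29 of the 50 genes were lower. A milder response of the IMQ+celastrol skin to imiquimod may be a biological explanation, and so may a stronger one in the single IMQ animal or library, which enters both comparisons. Neither was tested.

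Growing-hair follicle cells were seen almost only in the normal library. For cells with inner follicle keratin genes, placement of IMQ cells in other clusters is argued against. Of the IMQ cells, 0 had 3 or more of 7 such genes (upper limit 0.0492%), against 738 normal cells (7.20%). This check does not cover the unnamed clusters 4, 20 and 25, which other genes lead. Krt79 and Defb6, leading genes of cluster 25, are also among those of cluster 3, with 17 normal and 448 IMQ cells. Placement of such cells in other clusters was not tested. Loss of whole follicles with their glands stays open. The sebocyte-like share was lower in the IMQ library by a factor of 5.58 (3.81 to 8.47), against a lower bound of 76.5 for follicle keratinocyte-like cells. Several unnamed clusters with follicle genes among their leading genes were also nearly absent: cluster 4 (Krt15 and Krt17) went from 8.63% in the normal to 0.293% in the IMQ library, cluster 25 (Krt79 and Krt17) from 4.06% to 0.0267%, and cluster 20 (Wif1 and Vcan) from 5.23% to 0 cells, and cluster 22 (histone genes and Krt28) from 525 to 0 cells. The basal keratinocyte-like cluster 23, with Sox9, Sostdc1 and Krt15 among its leading genes, was lower by less, at 2.001% of the normal and 0.841% of the IMQ cells, and stood at 3.78% of the IMQ+celastrol cells. Loss of whole follicles, another hair-cycle phase of the animal sampled and an effect of the treatment cannot be told apart, since the number of libraries per group was 1. A shallower piece of skin may also contribute and was not tested.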

How the results depend on the processing

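The setting named "each cluster by its highest score", the single doublet rate and the level limit for high and low genes were chosen after seeing the data, and the other settings before it. Of 742 values recomputed for 84 results, 518 stayed within the counting interval, 220 moved beyond it and 4 reversed in sign. A reversal was counted only where the interval of the reported log2 ratio left out 0. Shares of cells with Lrp1, given in percent, could only stay or move. Of the 209 values of the 24 main results, 127 stayed, 80 moved and 2 reversed, 10 of the moved or reversed ones by more than 1.5-fold. Among the 395 values of single named genes, 293 stayed, 101 moved and 1 reversed, and 57 of the 395 differed by more than 1.5-fold, at most by 7.82 in log2. These belonged to 27 of 44 gene results. For IMQ over normal they were Krt77, Lor, S100a8, S100a9, Sema3d, Sprr2d and Sprr2i (keratinocyte), Acan, Cxcl13, Lcn2, Saa3 and Stmn2 (fibroblast) and Ccl8, Cd209f, Chil3, Mmp8 and Wfdc21 (monocyte or macrophage). For IMQ+celastrol over IMQ they were Ccl27a, Krt15 and Mt4, Cfd and Hp, and Ccl5, Coch, Ifit1, Igfbp5 and Saa3, in the same order of classes. These labels rest on counting error alone, which is narrow at this depth, and the cause was not tested for any move. Values are log2 ratios, given as IMQ over normal and then IMQ+celastrol over IMQ where both moved, and "high" and "low" name the 50 genes highest and lowest in IMQ over normal. As reported, the shares stood at -0.12 and 0.82 (keratinocyte), 0.53 and -0.24 (fibroblast), 2.45 and -2.13 (monocyte or macrophage) and 4.75 and -0.69 (neutrophil), and the lists at 4.48 and -1.05 (epidermal activation), -0.20 and 0.74 (fibroblast interferon) and 1.04 and -0.25 (fibroblast chemokine). With median-of-ratios scaling, epidermal activation was 4.61 and -1.09, interferon in the celastrol comparison 0.60, fibroblast high genes -1.79, and fibroblast Lrp1 1.41 and -0.58. With the mean over cells, epidermal activation was 4.72 and -1.33, interferon in the IMQ comparison -0.37, keratinocyte high and low genes -1.91 and 1.83, and fibroblast Lrp1 1.18 and -0.54. With 10 CPM added, epidermal activation was 4.30 and -0.98, interferon in the celastrol comparison 0.44, and chemokines 0.19 and -0.064. With all members of at least 1 UMI, chemokines were 0.78 and -0.091. With 200 genes, high and low genes were -0.88 and 0.99 in keratinocyte-like and -1.08 and 0.83 in fibroblast-like cells, and low genes 0.19 in monocyte or macrophage-like cells. Without the split, high and low genes were -1.82 and 1.79 in keratinocyte-like cells, and high genes -1.72 in fibroblast-like cells.

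With a limit of 10% on mitochondrial UMIs, the keratinocyte share was -0.54 for IMQ over normal, the fibroblast share -0.12 for IMQ+celastrol over IMQ, epidermal activation 4.70 and -1.11, interferon in the celastrol comparison 0.61, keratinocyte high and low genes -1.80 and 1.83, fibroblast high genes -1.82 and fibroblast Lrp1 -0.58. With 500 genes per cell, the keratinocyte share was -0.54, epidermal activation 4.71 and -1.12, keratinocyte high genes -1.84 and fibroblast Lrp1 -0.53. With called doublets kept, the keratinocyte share was -0.54, the monocyte or macrophage share 0.87, epidermal activation 4.73 and -1.11, keratinocyte high genes -1.78, and in monocyte or macrophage-like cells high and low genes -1.01 and 0.23 and Lrp1 1.66 and -0.92. At resolution 2, the keratinocyte share was -0.36, epidermal activation 4.99 and -1.11, keratinocyte high and low genes -1.83 and 0.84, fibroblast high genes -1.77 and fibroblast Lrp1 -0.55. With each library clustered by itself, the keratinocyte share reversed to 0.10 for IMQ over normal and was 0.12 in the celastrol comparison, the T cell share reversed from 0.60 to -0.029, the fibroblast share was 0.40 and -0.048 and the monocyte or macrophage share 2.17 and -1.76. There, epidermal activation was -1.003 in the celastrol comparison, high and low genes -1.49 and 1.81 (keratinocyte) and -0.44 and 0.92 (monocyte or macrophage), fibroblast high genes -1.89 and fibroblast Lrp1 -0.57. That setting gave no neutrophil share for IMQ over normal, since no cluster of the normal library took that name. With doublets at a single rate, epidermal activation was 4.58 for IMQ over normal and Coch in monocyte or macrophage-like cells reversed to -0.87. With each cluster named by its highest score, the keratinocyte share was -1.09, the fibroblast share 0.43 and -0.094, epidermal activation 4.84, and fibroblast interferon reversed to 0.027 for IMQ over normal and was 0.61 in the celastrol comparison. With only genes at 0.5 or more of their level over all kept cells, keratinocyte high genes were -1.45, fibroblast high and low genes -1.73 and 0.88, and monocyte or macrophage low genes 0.39. The single doublet rate and naming by highest score were not run for Lrp1 and for the high and low genes. No paired analysis was possible because each group had 1 library and no result comes from a test. Depth limited the 140 normal and 108 IMQ+celastrol cells of the monocyte or macrophage-like class, with class totals of 359909 and 583734 UMIs against 3706353 in the IMQ library.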

Other observations

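Pericyte or smooth muscle-like cells, the contractile cells around vessels, numbered 250, 605 and 584 in the normal, IMQ and IMQ+celastrol libraries. Their cell cycle genes were higher in the IMQ+celastrol than in the IMQ library for 17 of 20 measured members and lower for none (median log2 ratio 1.64, percentile 100), with the mitotic genes Ube2c at 14.2-fold (9.82 to 21.4), Mki67 at 7.17-fold (4.84 to 10.97) and Top2a at 6.14-fold (4.54 to 8.46). The counts came from few cells: 33 IMQ+celastrol cells with at least 20 UMIs of the list held 82.9% of its 5072 UMIs, and 12 such cells held 50.2% of the 1950 UMIs in the IMQ library. Matrix genes of the same class were higher in the IMQ than in the normal library for 13 of 22 members and lower for 3 (0.69), with Tnc 6.10-fold higher (4.27 to 9.015) and Col3a1 2.68-fold higher (2.53 to 2.84), whereas in fibroblast-like cells of these libraries 10 of 22 were lower and 5 higher. The difference between the classes was not tested. Immediate early genes were lower for 10 of 18 members (-0.78).

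T cell-like cells differed in lists that the report did not give. Heat shock genes were higher in the IMQ than in the normal library for 9 of 14 members (0.71), and their median between IMQ+celastrol and IMQ was -0.42. The summed level of the interferon response list in these cells was 1123 CPM in the normal library, 386 in the IMQ library and 581 in the IMQ+celastrol library, and in fibroblast-like cells 1210.1, 935 and 1714 CPM.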
